A study of Mus musculus with 2 samples.

How the data were processed

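H3K9me3 ChIP-seq was analysed from 4 deposited peak lists of mouse embryonic liver: 1 per replicate, 1 called on both replicates together and 1 of replicated peaks. Per the labels, both replicates are biological, from pooled embryos of the B6NCrl strain at embryonic day 16.5, and the genome build is mm10. Per the text files deposited with the samples, each list was made from filtered alignments of the ChIP reads together with 2 control files, and the replicated list was derived from the other 3; the peak caller, the filters and the overlap rule are not given in the sources used here. The control reads were not analysed here. No read counts are in the files, so no test or interval over reads was used; intervals for counting error concern numbers of peaks. A depth relative to the control was estimated only from the grid of fold values and the smallest peak widths, for the closing section.

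The authors' deposited lists give for each peak its start, end and summit, a display score of 10 to 1000, which was not used, a fold enrichment (ratio) over the control, and −log10 p and −log10 q values. These values are the authors' own and belong to each list: they were used to describe, rank or filter peaks within a list, and set side by side for the same peak in the 2 replicates. The lowest −log10 p in the replicate lists was 2.01. Such a p says how far a peak stands above the control, not how replicates vary.

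Coordinates were compared with the GRCm38 reference sequence, the build called mm10: all peak ends fell within the lengths of chromosomes 1 to 19, X and Y. Genes were the 21938 protein-coding and 10155 long noncoding genes of GENCODE M21 (basic set) on these 21 chromosomes. Assembly gaps of at least 1000 bp were removed from all shifts and lengths. Peaks on scaffolds outside the chromosomes (167 of the replicated list) were left out of all comparisons with genes or shifts. The tissue was the only group, so no test between conditions was possible. Replicates were compared by the percent of peaks that touched by at least 1 bp, the bp Jaccard index and 1000 circular shifts of one list within each chromosome. A circular shift keeps the widths and the clustering of peaks. Location classes took the peak midpoint in the order promoter (within 1 kb of a transcription start), 5′ UTR, coding exon, 3′ UTR, other exon, intron, intergenic. For the gene lists the number of genes with a replicated peak in the body or within 2 kb was set against 10000 shifts. Adjusted p-values are Benjamini-Hochberg values over the 7 classes or the 15 lists, with a threshold of 0.05. The position test shifted peaks within each gene body, 10000 times.

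The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The lists are KRAB-type zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, imprinted, germline, X and Y ampliconic or reproductive homeobox, hepatocyte, postnatal liver enzyme and secreted protein, erythroid, other liver cell type, neuronal and muscle, housekeeping, and H3K9 methylation machinery genes. Zinc finger genes were taken by symbol, so the list holds some without a KRAB domain. Of 46 imprinted names 45 were in the annotation, of 30 erythroid names 29 and of 29 machinery names 28. The text names, for each list, up to 4 members with the highest fold of a replicated peak (up to 12 for the imprinted and machinery lists) and the number of the rest, the 10 replicated peaks with the highest fold and the 5 widest, and the 10 protein-coding genes with most bp under replicated peaks.

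The alternatives were other overlap rules (50% of a peak, or of both), stricter peaks (−log10 q of at least 2, fold of at least 4), equal numbers of peaks per replicate, peaks within 1 kb merged, each replicate left out, the list called on both replicates, the stronger 50% of replicated peaks, other gene regions, other null models (Fisher's exact test, lists matched on gene length, shifts along the whole genome), a minimum of 500 bp, wider promoters, bp in place of midpoints and autosomes only. Leaving out a replicate means using the other replicate's list at −log10 q of at least 2. The uniqueness of sequence was measured by counting each 31-base word of the peaks and of the last exons of coding genes in all chromosomes and scaffolds, on both strands.

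The tests were checked on simulated data. With no effect planted, 1.0% of gene lists had a p of 0.05 or less in 20 simulations. These peaks were random shifts like those of the null, so that rate cannot show whether shifts suit real peaks. With 20% of the genes planted, the zinc finger, hepatocyte and imprinted lists were recovered in 100% of the simulations. Planting 20% of shared peaks in a list of 27490 gave 20.9% shared, and none gave 0.837%. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and matplotlib 3.10.9 were used.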

Results

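Trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of silenced chromatin, was mapped by ChIP-seq in mouse liver at embryonic day 16.5, when the organ holds hepatocyte precursors and is also a main site of red blood cell formation. The data are 1 group of 2 biological replicates, each a pool of livers from male and female embryos; replicate 2 came from 41 embryos. There is no second condition, so the comparisons are replicate against replicate and peaks against the genome. The replicate lists held 27717 peaks (replicate 1) and 47334 peaks (replicate 2), a list called on both replicates together held 5336 and a list of replicated peaks 3900. Read totals are not given in the files, so the depth behind each value is known only from the peak values. The called peaks were narrow, with a median width of 196 bp in replicate 1, 212 bp in replicate 2 and 261 bp among the replicated peaks. The smallest widths, 170 bp in replicate 1 and 185 bp in replicate 2, were those of 25.1% and 27.2% of their peaks. Widths thus partly reflect the calling and do not give the extent of marked domains. Many peaks were weak: 25.6% of the replicated peaks passed a q of 0.05 (−log10 q of at least 1.3).

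The replicated peak with the highest fold enrichment was at chromosome X, 170674182 to 170675296 (mm10), over an exon of Asmt, which encodes the last enzyme of melatonin synthesis; its fold enrichment over control was 14.6, with 14.8 in replicate 1 and 14.2 in replicate 2. A neighbouring peak over Asmt reached 10.6. An intron of Tmem267 on chromosome 13 (119597568 to 119598233) reached 9.52, exonic sequence of Trim56, an antiviral ubiquitin ligase, on chromosome 5 (137112537 to 137115248) 9.17, Gm21887 on chromosome X (170008961 to 170010028) 8.04, a site 3456 bp from Vmn1r238 on chromosome 18 7.92, and exonic sequence of Tcfl5 on chromosome 2 7.68. The remaining 3 of the top 10, with folds of 9.91, 8.25 and 7.80, lay on scaffolds outside the chromosomes. Of the 31-base words in the Gm21887 peak 0% occur once in the genome, against 86.4% in the top Asmt peak, 79.7% in the Tmem267 peak and 99.7% in the Trim56 peak, so reads at Gm21887 cannot be placed there alone. The widest replicated peak, of 5581 bp, lay on a scaffold; the next widest covered the end of Plec (4474 bp), which encodes plectin, an exon of the noncoding gene Gm26917 (3661 bp, fold 1.95), the zinc finger gene Zfp180 (3403 bp) and Il3ra (3023 bp). The Gm26917 peak combined its low fold with a −log10 q of 18.7, close to the 18.9 of the Trim56 peak.

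Of the peaks on chromosomes 1 to 19, X and Y, 6390 of 27490 replicate 1 peaks (23.2%) touched a replicate 2 peak, and 6363 of 47081 replicate 2 peaks (13.5%) touched a replicate 1 peak. Circular shifts of one list along the chromosomes gave means of 0.927% and 0.540%. The bp Jaccard index was 7.68% against 0.172% for shifted peaks. Each of these values lay above all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give). Sharing was 25.1 times the shifted value for replicate 1, although most peaks of either list had no counterpart in the other. The shifts match neither the control signal nor where reads can be placed. Peaks that coincide for such reasons would count as shared too, and how many do was not tested. Among peaks with −log10 q of at least 2, 38.0% of 1168 replicate 1 peaks and 10.3% of 4220 replicate 2 peaks were shared.

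Across the 3647 replicated peaks that touched a peak in both replicate lists, Pearson's r of log2 fold enrichment was 0.354 and Spearman's rho 0.217; this is a correlation across peaks, which are not independent replicates. The median difference of log2 fold enrichment, replicate 1 less replicate 2, was 0.01, with an SD of 0.38. The peak over Cdkn1c, for example, had a fold of 4.86 in replicate 1 and 7.72 in replicate 2, and that over Zfp35 had 6.21 and 4.39.

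**Figure D1:**
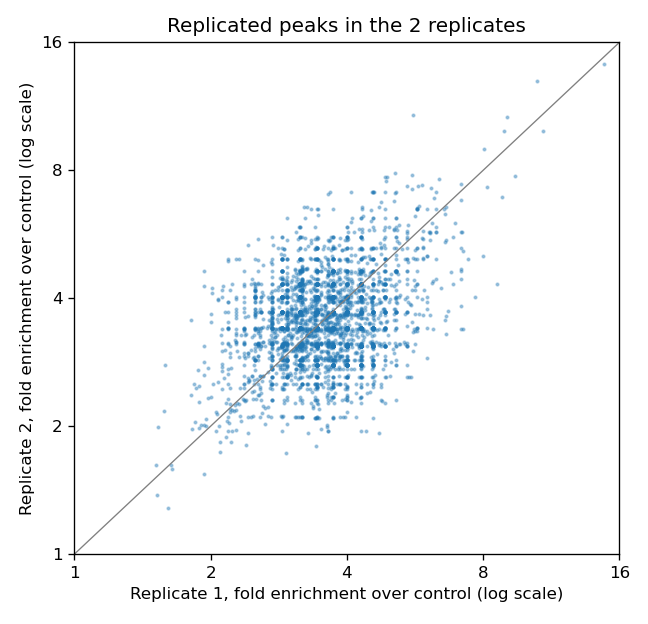
Fold enrichment over control of the 3647 replicated peaks in replicate 1 (horizontal axis, log scale) and replicate 2 (vertical axis, log scale); each point is 1 peak, with the value of the best overlapping peak in each replicate list, and the line marks equal values. Points spread widely around the line at folds of 2 to 8 (Pearson's r 0.354 on the log2 scale).

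All 3900 replicated peaks were present, with identical positions and values, in the list called on both replicates together, of which they made up 73.1%. Of the list called on both, 83.8% of peaks touched a replicate 1 peak and 87.1% a replicate 2 peak. Its peaks with −log10 q of at least 1.3 were in the replicated list in 96.9% of cases, and its weaker peaks in 67.4%. The rule behind the replicated list is not given in the sources used here: all 3622 peaks that overlapped a peak of both replicates over 50% of either peak were in it, as were 278 that did not meet this.

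Chromosome 5 carried the highest density of replicated peaks, 3.42 per Mb of sequence without gaps, or 2.23 times the autosomal density of 1.53. Chromosome 4 followed with 2.34 per Mb and chromosome 17 with 2.27, while chromosome 3 was the lowest autosome with 0.774. Chromosome X carried 0.324 per Mb, or 0.211 times the autosomal density, and chromosome Y 0.0454 per Mb. Of the sequence without gaps, 46.7% is soft-masked on X and 96.3% on Y, against 30.6% to 35.8% on the autosomes. The pools held male and female embryos, so X and Y, outside the region they share, were present in fewer copies than autosomes. The densities were corrected for neither masking nor copy number. Whether the chromosome X peaks named above lie in the shared region was not examined. In the replicate lists, chromosome 5 stood at 1.70 (replicate 1) and 1.47 (replicate 2) times the autosomes, and chromosome X at 0.126 and 0.436. The replicates thus differed on chromosome X in the full lists (odds ratio of X to autosomal peaks, replicate 2 over replicate 1, 3.47, 95% interval 3.02 to 3.99 for counting error only), and among peaks with −log10 q of at least 2 this odds ratio was 1.13 (0.713 to 1.79). Chromosome Y carried 7 peaks in replicate 1 and 5 in replicate 2, an odds ratio of 0.426 (0.135 to 1.34); among peaks with −log10 q of at least 2 it carried 5 and 4, an odds ratio of 0.221 (0.0593 to 0.825). The densest 1 Mb window, chromosome 4 from 152249135 to 153249134, which holds Nphp4, Chd5 and Kcnab2, contained 51 replicated peaks. The next, chromosome 5 from 127618001 to 128618000, which holds Tmem132d, contained 47. Chromosomes 5, 4 and X were picked out after their values were seen.

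**Figure D2:**
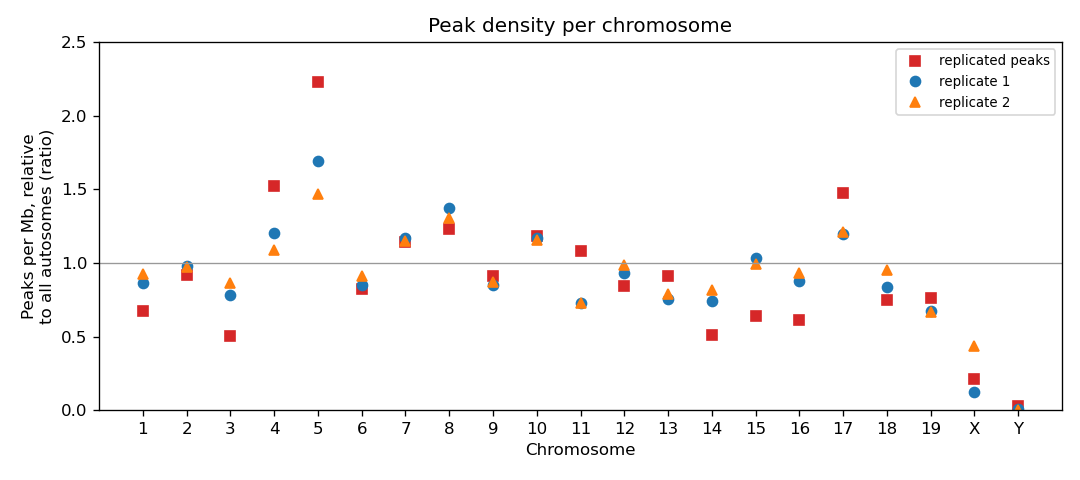
Peaks per Mb of sequence without gaps on each chromosome, divided by the density over all autosomes (vertical axis, ratio), for the replicated peaks (squares), replicate 1 (circles) and replicate 2 (triangles). Chromosome 5 stands highest in all 3 lists, at 2.23 in the replicated list, and chromosomes X and Y lie lowest.

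Coding exons and promoters held more replicated peaks than shifted peaks did. The shifts did not match GC content, and the classes were not tested without the zinc finger genes described below. Of the 3733 replicated peak midpoints on the chromosomes, 237 (6.35%) lay in coding exons against a shifted mean of 1.24%, a ratio of 5.10, and 175 (4.69%) within 1 kb of a transcription start against 2.90%, a ratio of 1.62 (both two-sided permutation p = 0.002, the smallest 1000 shifts can give; adjusted p = 0.00699 over 7 classes). By the same permutation test, introns held 38.9% (shifted 42.8%, adjusted p = 0.0594), intergenic sequence 47.9% (51.4%, adjusted p = 0.109), other exons 0.696% (0.391%, adjusted p = 0.0559), 3′ UTRs 1.39% (1.25%, adjusted p = 0.559) and 5′ UTRs 0.107% (0.0371%, adjusted p = 0.138), and none of these 5 classes passed. Their calls depended on the setting: with bp in place of midpoints intergenic sequence (ratio 0.837), other exons (1.90), 3′ UTRs (1.51) and 5′ UTRs (3.76) passed. At −log10 q of at least 2 intergenic sequence passed in opposite directions, 0.830 with replicate 1 alone and 1.08 with replicate 2 alone. The ratio of other exons, 1.78 in the replicated list, was then 1.09 with replicate 1 alone and 1.11 with replicate 2 alone, and passed in neither. In the full replicate lists the coding exon ratio was 1.82 (replicate 1) and 1.56 (replicate 2), and the promoter ratio was 0.826 and 0.930, which turns the direction for promoters; intergenic sequence (1.18 and 1.19) and 3′ UTRs (0.708 and 0.622) turned as well. With replicate 2 alone at −log10 q of at least 2 the coding exon ratio was 3.23.

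KRAB-type zinc finger genes, a large family of DNA-binding repressors, carried replicated peaks far more often than shifted peaks placed them there. A replicated peak touched the gene body or the 2 kb flanks of 87 of 423 such genes (20.6%), against 16.4 under shifts, a ratio of 5.31 (two-sided permutation p = 0.0002, the smallest 10000 shifts can give; adjusted p = 0.001 over 15 lists). The highest folds were over Zfp865 (6.41; replicates 5.87 and 7.39), Zfp27 (6.23; 6.57 and 6.49), Zfp35 (6.16; 6.21 and 4.39) and Zfp810 (5.65; 6.0 and 6.49), and 83 further members carried a peak. All peaks of the replicate lists gave 139 genes against 87.8 in replicate 1 and 175 against 128 in replicate 2. At −log10 q of at least 2 the ratio was 8.70 with replicate 1 alone and 3.25 with replicate 2 alone. With the promoter alone as the gene region the ratio was 1.99 and no longer passed (permutation test, adjusted p = 0.992).

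Within these zinc finger genes the peaks sat at the end of the gene, where the exon that encodes the zinc finger array usually lies. In the 77 genes of more than 1 exon with a peak in the body, the last exon held 58.8% of the 75.6 kb under replicated peaks and made up 9.28% of the gene sequence. Peaks shifted within each gene body put 17.5% there (one-sided permutation p = 0.0001, the smallest 10000 shifts can give). Zfp27, Zfp35 and Zfp810 had their highest peak in the last exon, for example chromosome 7, 29894119 to 29895957, in Zfp27. The highest peak of Zfp865 (chromosome 7, 5029891 to 5032016) covered another exon. The share was 57.0% for replicate 1 alone and 56.0% for replicate 2 alone, both at −log10 q of at least 2.

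Imprinted genes, which are expressed from 1 parental copy, carried replicated peaks at 22 of 45 members (48.9%) against 2.76 under shifts, a ratio of 7.98 (two-sided permutation p = 0.0002, the smallest 10000 shifts can give; adjusted p = 0.001). The highest was a peak of 2289 bp over Cdkn1c, an inhibitor of the cell cycle, at chromosome 7, 143459124 to 143461412 (fold 6.51), which covered the gene start. Gnas carried 11 peaks with a highest fold of 5.36, Grb10 reached 4.64 and Impact 4.49. Some members share a peak because they overlap or face each other: Kcnq1 and Kcnq1ot1 (4.49; 3.13 in replicate 1 and 5.87 in replicate 2), Peg3 and Usp29 (3.94), and Igf2r and Airn (3.90). Nespas reached 3.90, Blcap 3.67, and 10 further members carried a peak; the 22 genes shared 36 distinct peaks. All peaks of the replicate lists gave ratios of 2.44 and 2.06, and the list passed in both. The highest peak of Peg3 lay 644 bp from the gene start and that of Airn 688 bp.

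Germline genes, which are silent in somatic tissues, carried replicated peaks at 9 of 44 members (20.5%) against 1.86, a ratio of 4.84 (two-sided permutation p = 0.0002, the smallest 10000 shifts can give; adjusted p = 0.001). Piwil1 reached 4.26, Tdrd9 4.20, Dazl, which encodes an RNA-binding protein of germ cells, 3.90 with a peak across the gene start, and Tuba3a 3.79, and 5 further members carried a peak. The Tdrd9 peak lay in the flank past the gene end, 97.3 kb from the gene start, and touched no peak of replicate 1. The peak with the highest fold lay within 1 kb of the gene start in 4 of the 9 genes. At −log10 q of at least 2 the ratio was 3.02 with replicate 1 alone, which did not pass, and 3.04 with replicate 2 alone, which did (permutation test, adjusted p = 0.611 and 0.048). The peak with the highest fold passed a q of 0.05 in 4 of the 9 genes. All peaks of the replicate lists gave a ratio of 1.27 in each, and the list passed in neither (permutation test, adjusted p = 0.657 and 0.445).

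Clustered protocadherin genes, which encode adhesion molecules of neurons, carried replicated peaks at 31 of 57 members (54.4%) against 3.92, a ratio of 7.91, and missed the threshold after adjustment (two-sided permutation p = 0.0164, adjusted p = 0.0615). These 31 genes shared 8 peaks, since the genes of a cluster overlap; Pcdha1, Pcdha2 and Pcdha3 had the same highest peak (fold 3.92), Pcdhga1 reached 3.77, and 27 further members carried a peak. With the promoter alone as the gene region the list passed (ratio 35.3, permutation test, adjusted p = 0.002), as it did with all peaks of the replicate lists (ratios of 2.43 and 1.84).

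No list of liver genes passed with replicated peaks. Of 32 hepatocyte genes only Gc, which encodes the vitamin D-binding protein, carried a replicated peak (fold 3.19), against 0.789 under shifts (permutation test, adjusted p = 1). Of 200 genes of postnatal liver enzyme and secreted protein families 13 did, against 7.44 (permutation test, adjusted p = 0.607), and they touched 18 distinct peaks. The highest folds, all 3.87, came from 1 intron peak shared by Ugt1a10, Ugt1a5, Ugt1a6a and Ugt1a6b, of the bilirubin and drug glucuronidation locus. That peak touched no peak of replicate 1. These Ugt1a genes overlap, and each carried 13 replicated peaks over 5.43 to 5.44 kb. A further 9 members carried a peak. Of 29 erythroid genes 2 did, Ank1 (3.72) and Sptb (3.57), which encode parts of the red cell membrane skeleton, against 1.06 (permutation test, adjusted p = 1). Of 32 genes of other liver cell types Reln did (2.87), against 1.93 (permutation test, adjusted p = 1). The −log10 q values of the Gc and Reln peaks were only 0.00449 and 0. The ratio of the postnatal list, 1.75, was 3.92 with replicate 1 alone (permutation test, adjusted p = 0.103) and 6.14 with a minimum of 500 bp of peak, where it passed (permutation test, adjusted p = 0.045). The erythroid ratio, 1.89, was 5.24 with replicate 1 alone and 0.723 with replicate 2 alone, and the list passed in neither. All peaks of the replicate lists turned the direction for the erythroid list (0.522 and 0.724) and the hepatocyte list (0.637 and 0.687), and neither passed.

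The remaining lists did not pass with replicated peaks either. Of 1135 olfactory receptor genes 9 carried a replicated peak against 14.9 (permutation test, adjusted p = 0.748), with the highest folds at Olfr123 (3.77), Olfr479 (3.77), Olfr1419 (3.63) and Olfr774 (3.42) and 5 more members. Against random lists matched on gene length the olfactory list passed with fewer genes (ratio 0.453, permutation test, adjusted p = 0.033), while all peaks of the replicate lists gave more olfactory genes than shifts, a ratio of 1.45 in each, and did not pass (permutation test, adjusted p = 0.212 and 0.0648). Of 329 vomeronasal receptor genes 7 did against 8.67 (permutation test, adjusted p = 1), led by Vmn2r124 (3.92), Vmn2r53 (3.67) and Vmn1r42 and Vmn1r43, which share a peak (3.34), with 3 more. At −log10 q of at least 2 the vomeronasal ratio, 0.808 with replicated peaks, was 0.328 with replicate 1 alone and 0.761 with replicate 2 alone, and passed in neither. No Hox gene (0 of 39, against 0.516) and no gene of the X and Y ampliconic or reproductive homeobox families (0 of 68, against 0.410) carried one (permutation test, both adjusted p = 1). Of 32 neuronal and muscle genes Slc17a7 (3.79) and Rbfox3 (3.34) did, against 1.18, and of 30 housekeeping genes Ppia did (6.46, in the flank of the gene), against 0.695 (permutation test, both adjusted p = 1). The housekeeping ratio, 1.44, was 4.24 with replicate 1 alone and 1.19 with replicate 2 alone, both at −log10 q of at least 2, and passed in neither. All peaks of the replicate lists gave fewer housekeeping genes than shifts (ratios of 0.247 and 0.459), which did not pass. Of 28 genes of the H3K9 methylation machinery Atf7ip (4.39), Daxx (4.28) and Resf1 (3.34) did, against 1.45 (permutation test, adjusted p = 0.748). The Daxx and Resf1 peaks lay in the flanks. At −log10 q of at least 2 the machinery ratio, 2.06 with replicated peaks, was 3.92 with replicate 1 alone and 1.54 with replicate 2 alone, and passed in neither. All peaks of the replicate lists gave the opposite direction for this list, with ratios of 0.739 in replicate 1 (permutation test, adjusted p = 0.657) and 0.419 in replicate 2, where the list passed with fewer genes than shifted peaks gave (5 against 11.9, adjusted p = 0.03). Of all 21938 protein-coding genes, 1128 (5.14%) carried a replicated peak.

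**Figure D3:**
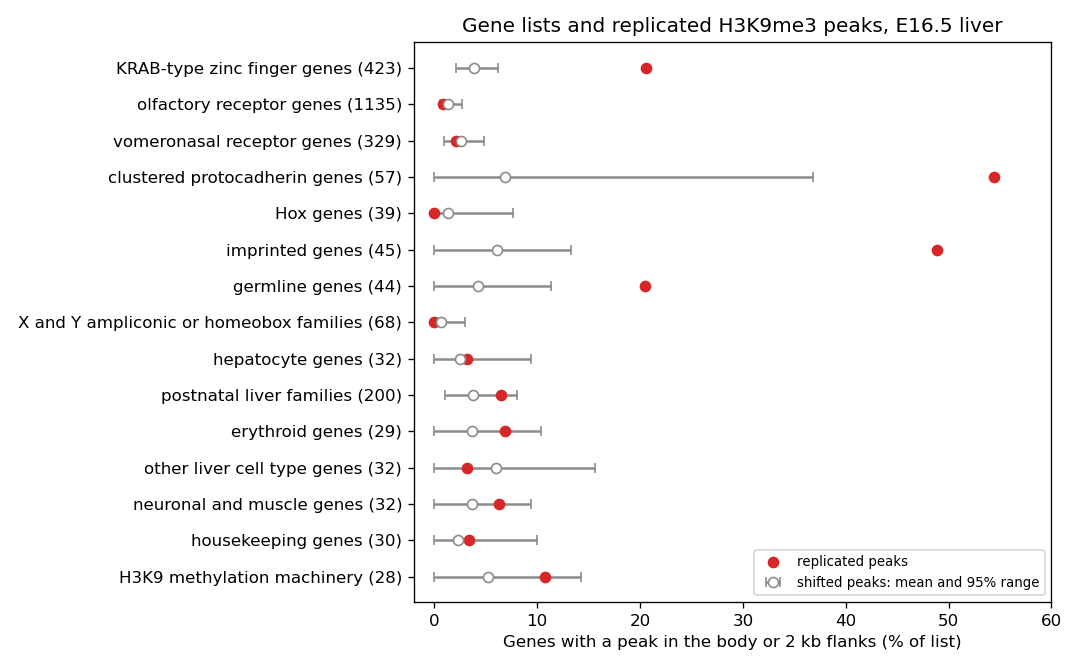
Percent of the genes of each of the 15 lists (number of genes in brackets) with a replicated peak in the gene body or its 2 kb flanks (filled points), and the mean and central 95% of 10000 circular shifts of the peaks (open points and bars). Imprinted genes (48.9%), KRAB-type zinc finger genes (20.6%) and germline genes (20.5%) lie beyond the bars and passed the adjusted test; protocadherin genes lie beyond the bar at 54.4% and did not pass after adjustment.

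Among protein-coding genes with the most sequence under replicated peaks were long genes with many weak peaks. Tmem132d on chromosome 5 carried 40 peaks over 11.4 kb, with a highest fold of 4.21, Cdh13, a cadherin gene on chromosome 8, 28 peaks over 7.47 kb, and Tmem132b 19 over 6.44 kb. Gm20388 ranked highest with 26 peaks over 12.4 kb, but its annotated body spans chromosome 8 from 119910841 to 124345722. Drg1 and Sfi1, neighbours that overlap on chromosome 11, carried 16 peaks over 11.1 kb and 12 over 8.66 kb with highest folds of only 2.72 and 2.17 at −log10 q of up to 24.5. Mroh2a carried 19 over 10.3 kb (highest fold 2.95), Plec 8 peaks over 8000 bp (6.79), Ugt1a7c 14 over 5.90 kb and Ugt1a10 13 over 5.44 kb (both 3.87).

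Replicated peaks held less repeat-masked sequence and more GC than shifted peaks. Soft-masked bases made up 23.0% of peak sequence against 33.9% under shifts, and GC content was 49.0% against 42.1% (both two-sided permutation p = 0.002, the smallest 1000 shifts can give). Replicate 1 alone at −log10 q of at least 2 gave 23.6% and 49.2%, and replicate 2 alone 23.1% and 48.1%. Peaks with under 50% of their 31-base words found once in the genome were 0.804% of replicated peaks and 14.8% of shifted peaks. Repeats with near-identical copies are thus hardly covered by the replicated peaks on the chromosomes. Shifts also land where reads cannot be placed uniquely, so the lower repeat shares do not show that the mark avoids repeats. Peaks on scaffolds are not included.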

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

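The tests of list length below were chosen after the result was seen, and the grid step was read from the 3 commonest fold values of each list after a reading from the 8 commonest, which are not all neighbours on the grid, had missed the deposited p-values. Replicated peaks on scaffolds outside the chromosomes number 167, on 16 scaffolds, and enter no comparison with genes or shifts. They stand out as peaks in sequence left out of the gene analysis. The uniqueness of their sequence was not measured. They make up 4.28% of the replicated list and cover 81.9 kb, and 56.9% of them have a −log10 q of at least 2, against 14.2% of replicated peaks on the chromosomes. Their median fold, 3.25, is slightly below the 3.34 of replicated peaks on the chromosomes.

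Replicated peaks over the last exons of zinc finger genes could come from base composition or from reads shared between gene copies. A replicated peak touched 58 of 414 last exons of zinc finger genes and 13 of 2070 last exons of other genes (0.628%) matched on length and GC content, a ratio of 22.3 (95% interval 12.3 to 40.3, exons taken as independent), which argues against GC content as the cause. Among exons in which at least 95% of the 31-base words occur once in the genome the rates were 17.5% of 240 and 0.417% of 1200. The ratio of 42.0 (16.8 to 105) argues against reads shared between copies that the reference sequence holds. Copies missing from it would not be counted. Before matching, a peak touched 9.25% of the 173 zinc finger exons that were not unique and 17.1% of the 245 that were. No biological explanation was tested, since the design holds 1 group.

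The list called on both replicates together (5336 peaks) is shorter than that of either replicate. Fold values of weak peaks fall on a regular grid, and if each is (reads × worth of a read + 1) / (background + 1), the grid gives a depth in units of the control depth: 1.11 for replicate 1, 0.945 for replicate 2 and 2.05 for the pool. Each depth also takes the smallest peak width as fragment length and the mean background per bp of replicate 1 and the pool as that of the control. The value of replicate 2 rests on this assumption, and so does the comparison with the sum below. The pool differs from the sum of the replicates by 0.0022%, and its depth is 1.85 times that of the deeper replicate, which argues against a loss of reads in the pool. A read was worth 0.487 in the pool, 0.902 in replicate 1 and 1.00 in replicate 2, the same order as the list lengths, so scaling the pooled reads down to the control is a candidate explanation: chance pile-ups of reads then rarely reach the threshold. The order holds for replicate 2 as well, although replicate 1 was by this estimate 1.17 times as deep, but 3 lists do not test whether scaling accounts for the longer list of replicate 2, which stays open.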

How the results depend on the processing

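Replicates left out here leave the other at −log10 q of at least 2; locations and gene lists in the full replicate lists, where promoters, intergenic sequence, 3′ UTRs and the machinery, olfactory, erythroid, hepatocyte and housekeeping lists turned direction in both replicates and the germline list did not pass, are not counted here. Sharing between the replicates, the excess of coding exons and promoters, the imprinted list, the position within zinc finger genes, and the soft-masked and GC content kept their direction and side of the threshold under these alternatives; the number of lists above expectation stayed within 1.5 times. Pearson's r was 0.44 with −log10 p. At 50% of the peak, 78.9% and 83.1% of the list called on both touched replicates 1 and 2. Leaving out a replicate gave chromosome 5 densities of 1.74 to 1.90 and chromosome 4 densities of 1.38 to 1.40 times the autosomes, and chromosome X 0.296 to 0.334. The zinc finger list lost its call with promoters only (1.99); the germline list did with 500 bp of peak (7.75), and without a replicate ranged from 3.02 (not past the threshold, replicate 1 alone) to 3.04. The protocadherin list passed in 6 of 10 alternatives, the olfactory list in 2, with fewer genes than expected, and the vomeronasal (fewer) and postnatal liver (more) lists in 1 each. Ratios of observed to shifted genes that turned direction among these alternatives were of lists that passed in neither setting: with replicate 2 alone olfactory 1.27, X and Y families 2.26, hepatocyte 0 and erythroid 0.723; with replicate 1 alone hepatocyte 0; with the list called on both X and Y families 1.80; with the stronger peaks vomeronasal 1.00 and hepatocyte 0; with gene bodies housekeeping 0 and machinery 0.740; with promoters hepatocyte, erythroid, neuronal and muscle, and machinery 0; with 500 bp hepatocyte 0; with whole-genome shifts vomeronasal 1.01; with Fisher's test hepatocyte 0.607 and housekeeping 0.648. Of the location ratios with replicate 2 alone, intergenic was 1.08 and passed (permutation test, adjusted p = 0.00932), 3′ UTR 0.998 and 5′ UTR 0. Classes that passed only in an alternative, in the main direction, were intron with replicate 2 alone (0.814) and the list called on both (0.893), intergenic (0.830) and 3′ UTR (1.93) with replicate 1 alone, other exon with the list called on both (1.71) and autosomes (1.80), and with bp the 4 classes in the report. The causes were not tested. Folds over named genes in each replicate list were an alternative chosen after seeing the data; with 2 values per gene they give no yardstick for change. No read totals are given, so what depth limits is unknown.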

Other observations

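Replicated peaks crowded the distal ends of the mouse chromosomes, away from the centromere, a pattern looked for after the dense windows of chromosomes 4 and 5 were seen. Those windows lie in the distal part and were kept in all values below. The p-value and the interval are thus not independent of the windows that prompted the question. The distal 20% of the chromosomes held 40.9% of the replicated peaks, against 20.0% under circular shifts (two-sided permutation p = 0.002, the smallest 1000 shifts can give), 33.4% and 29.8% of all peaks of replicates 1 and 2, and 39.2% and 36.0% of those with −log10 q of at least 2. Distal sequence is richer in GC, which might account for this. Autosomal 1 Mb windows in the distal part held 2.76 times as many replicated peaks as the others; averaged over 4 equal-sized GC classes of the windows the ratio was 1.91 (95% interval 1.34 to 2.61 from resampling chromosomes), and over 20 GC bins 1.94. GC content at this scale thus accounts for part of the excess at most; no biological explanation was tested.

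Whether zinc finger genes outside the fixed list carry replicated peaks more often than shifts is a hypothesis that stayed open for a modest excess only. Of 87 protein-coding genes with a RefSeq zinc finger protein product and a symbol outside the list, 7 carried a replicated peak against 5.32 under shifts, a ratio of 1.32 (95% interval 0.529 to 2.71 for counting error, two-sided permutation p = 0.551). They were Zfpm1 (fold 5.73), Rbak (3.81), Gm35315 (3.78), 3300002I08Rik (3.48), Gm10778 (3.48), Dzip1 (3.17) and Ikzf3 (2.73), named after their values were seen. The set is small and mixes classes of zinc finger, and the interval holds both no excess and a modest excess but lies below the ratio of 5.31 of the fixed list.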
